A study of Mus musculus with 11 samples.

How the data were processed

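RNA of mouse tibialis anterior muscle was measured on 11 Affymetrix arrays in 4 groups: innervated control (3 arrays), denervated control (3), innervated mutant (2) and denervated mutant (3). The deposited values are probe set signals in intensity units on a linear scale; the authors had scaled each array to the same 2% trimmed mean of 2500, as the values themselves show, and the software that made them is not given in the sources used here. The table held 45101 probe sets and no array outside the 4 groups. Groups were taken from the sample titles. The labels give no scan date or batch and do not say whether equal replicate numbers mark a shared animal. Deviations from the group means correlated at 0.11, 0.22 and 0.30 across probe sets between denervated and innervated control arrays of equal number, and at -0.18 to 0.10 in the other groups, so a block was tried.

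The signals were used as log2(value + 16) without further normalization, since the trimmed means lay within 10% of each other, the tolerance that was set. Probe sets above their own array's median on at least 2 of the 11 arrays were kept. The 64 Affymetrix control probe sets were left out of the tests, a choice that was not part of the plan, which left 26170 probe sets. The supplied annotation listed 35890 probe sets, of which 34958 had exactly 1 gene symbol, 932 had several and 9211 probe sets were not listed. Of the gene IDs, 34754 matched the reference gene table and 0 symbols needed updating. Where genes were counted or named, each of the 12214 genes was represented by its kept probe set with the highest mean. Listed genes without a tested probe set are not analysed here.

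Groups were compared with limma 3.58.1 in R 4.3.3. A model with a mean per group was fitted to all 11 arrays, with moderated variances (eBayes with trend) and Benjamini-Hochberg adjustment over the kept probe sets of each comparison, at a threshold of 0.05 and no minimum fold. The 5 comparisons were denervated minus innervated muscle in control and in mutant, mutant minus control in denervated and in innervated muscle, and the interaction, which is the denervation change in mutant minus that in control. The error of a log2 change is the standard error of the fit; the error of a signal is the standard deviation between arrays of a group. Single values were compared with exact two-sided permutation tests, for which 3 against 3 arrays allow no p below 0.1.

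The tests, the lists, the naming rule and the first group of alternatives below were fixed before the data were examined. There were 25 lists of muscle, metabolic, stress and cell type genes, of which 22 had at least 3 tested members. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. With the estimated correlation 4 of 16 calls held for denervation in control, 7 of 15 for denervation in mutant and 0 for the other comparisons. That setting also ended calls of lists whose estimated correlation lay below the preset 0.01. Satellite cell genes (-0.03) went from camera adjusted p = 0.009 to 0.15 between genotypes in denervated muscle. A call lost in this way therefore does not by itself show correlated genes. Of the 426 genes tested in the lists, 3 stand in more than 1 list: Cdkn1a, Gadd45a and Runx1. How many marker genes of other cell types muscle fibres themselves express was not tested. Members past the threshold were counted over all tested probe sets and with the p adjusted over the list alone.

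The named genes followed a rule. After Runx1, these were the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap between the groups (by chance 10% of genes do not overlap with 3 against 3 arrays, and 20% with 3 against 2), and from each list up to 4 members with the smallest p. No overlap rule applied to the interaction. Where fewer than 5 genes passed, the 5 with the smallest p were named. Correlations of changes across probe sets describe the data and carry no p.

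The pipeline was tested on simulated arrays with the real means and spreads, in which 200 of 26170 probe sets were changed. For denervation in control 32% of changes of 1 and 85% of changes of 2 log2 units were recovered, with 5 false calls. For the interaction these were 10% and 53%, with 3 false calls. Each comparison was simulated in a single run, and these shares hold for 200 changed probe sets. Denervation in control and genotype in denervated muscle were simulated alike, with 3 against 3 arrays. Their 32% and 42% for changes of 1 log2 unit therefore differ only between runs. Denervation in control called 7670 in the real data, so its 32% and 85% do not describe that comparison. In the real arrays genes of a list could vary together, with estimated correlations from -0.03 (satellite cell genes) to 0.75 (fast-fibre genes). The simulated errors were drawn independently for each probe set and array, so the false calls may be too few. The trp control probe sets, which match a bacterial gene, read between 13.8 and 440 and were taken as the range of background.

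Alternatives to these choices were quantile normalization, median scaling, pseudocounts of 1 and 64, no filter or a stricter filter, one probe set per gene, eBayes without trend, array weights, only the arrays compared, a block for the replicate number, a minimum of 1.5-fold and leaving out each array in turn. Alternatives added after the data were seen were a pseudocount of 512, centring on the hybridisation spike-in RNAs, the 5'-to-3' ratio of spiked RNAs as a covariate, a block in the control arrays alone, camera on the fit without trend and median scaling for the lists. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.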

Results

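Total RNA of mouse tibialis anterior, a fast muscle of the lower leg, was measured on 11 Affymetrix arrays with 45101 probe sets each. The control genotype carried a floxed and a null allele of Runx1, a transcription factor gene. The mutant genotype carried MCK::cre in addition, in which the muscle creatine kinase promoter drives Cre recombinase in muscle fibres. The muscle was either innervated or, per the sample titles, denervated for 3 days, which gave 3 innervated control, 3 denervated control, 2 innervated mutant and 3 denervated mutant arrays. The treatment note of denervated control 3 gives 5 days, so counts without that array are given beside the main ones. The median signal per array lay between 442.5 and 604.6 and the maximum between 172000 and 304200, and the number of arrays limits the precision. Denervated and innervated arrays separated on the first principal component, which held 51.6% of the variance, against 10% for the next. The labels do not state that the replicates of a group are separate animals, so each p measures the spread between samples. The comparisons ask how muscle responds to denervation, and which part of the response differs in the mutant genotype. Only the mutant carried MCK::cre, so an effect of Cre cannot be told apart from one of targeting Runx1.

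Runx1 itself was strongly induced by denervation. Its brightest probe set rose from a signal of 400.8 ± 192.3 (SD, n = 3) to 24583 ± 1216 (SD, n = 3) in control muscle, a 64.9-fold rise (log2 change 6.02 ± 0.30 SE, limma adjusted p = 2.84e-08). In mutant muscle it rose from 341.6 ± 75.5 (SD, n = 2) to 21346 ± 1593 (SD, n = 3), a 60.3-fold rise (log2 change 5.91 ± 0.34 SE, limma adjusted p = 1.20e-07). The innervated means of both genotypes lay within the signal range of the trp control probe sets (13.8 to 440), so the size of these folds rests on background: with a larger pseudocount, added after the data were seen, the log2 changes were 4.80 and 4.68. The genotypes differed by -0.21 ± 0.30 in denervated muscle (limma adjusted p = 0.884) and by -0.10 ± 0.34 in innervated muscle (limma adjusted p = 0.998), and the interaction was -0.11 ± 0.46 (limma adjusted p = 0.98). Of its 5 other probe sets, 4 also rose in control muscle. Another probe set, of low signal (988.8 ± 153.6 in innervated control muscle, SD, n = 3), rose by 1.29 in control muscle (limma adjusted p = 0.00177) and had a log2 change of -0.14 in mutant muscle (limma adjusted p = 0.759), with a genotype difference of -0.82 in denervated muscle that did not pass (limma adjusted p = 0.165). A further probe set, at 3442 ± 713.1 (SD, n = 3) in denervated control muscle, differed by -1.07 between genotypes there (limma adjusted p = 0.427). Exact two-sided permutation tests of 3 against 3 arrays cannot go below p = 0.1, the value they gave for denervation in control muscle with the brightest probe set. They gave 0.1 for genotype in denervated muscle too, with that probe set and with both probe sets just described. On the brightest, the denervated mutant arrays (20402.8 to 23185.2) all lay below the denervated control arrays (23499 to 25898.2). Where these probe sets lie relative to the deleted part of the gene is not known here, so the level of Runx1 checks nothing about the deletion.

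Among the largest rises with denervation of control muscle were acetylcholine receptor subunits, keratins and a channel regulator, and among the largest falls potassium channel subunits and a water channel. Rrad, a Ras-related GTPase that inhibits voltage-gated calcium channels, rose 345-fold (log2 change 8.43 ± 0.59 SE, n = 3 and 3), and Krt18 and Krt8, partner keratins of simple epithelia, rose 129-fold and 102-fold. Chrng and Chrnd, the fetal gamma and the delta subunit of the acetylcholine receptor, rose 116-fold and 56.8-fold. Myog, a myogenic transcription factor, rose 66.2-fold (log2 change 6.05 ± 0.24 SE), Nrcam, a neuronal adhesion molecule, rose 77.5-fold, and Gdf5, a ligand of the bone morphogenetic protein family, rose 63.2-fold. Kcng4, a potassium channel subunit, was 60.3-fold lower, Perm1, a regulator of oxidative genes in muscle, fell by 5.73 ± 0.24 (log2, SE) while its other probe set changed by 0.06 (limma adjusted p = 0.922), and Aqp4, the water channel of the fibre membrane, was 49.2-fold lower. Smco1 was 35.9-fold lower, Ky, a Z-disc-associated protein, 27.1-fold lower, Kcnc1, a voltage-gated potassium channel, 26.9-fold lower, and Atp1b4, Lrrc38, Mlf1 and Dhrs7c were between 26.8-fold and 18.6-fold lower. The limma adjusted p of the genes named so far lay at or below 0.000104. In all, 7670 of 26170 probe sets changed (limma), 3892 up and 3778 down, or 4202 of 12214 genes. The lower group mean of Rrad, Chrng, Chrnd, Krt8, Nrcam, Gdf5, Kcng4, Aqp4, Smco1, Atp1b4 and Lrrc38 lay within the signal range of the trp control probe sets (13.8 to 440), so the size of these folds rests on background.

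The fixed gene lists group these changes. Of 15 tested acetylcholine receptor and synapse genes, 7 rose (8 adjusted over the list alone), 2 fell and 6 did not pass. Their median log2 change was 0.70 (camera adjusted p = 0.0014, and adjusted p = 0.046 with an estimated correlation). They included Chrna1, the alpha subunit, up 20.3-fold, and Chrnb1, the beta subunit, up 4.32-fold. Of 16 denervation-responsive transcription and signalling genes, 10 rose (11 adjusted over the list alone), 3 fell and 3 did not pass, among them Cdkn1a, an inhibitor of the cell cycle, up 15.6-fold, and Gadd45a, a growth arrest gene, up 13.4-fold. Their median was 1.87 (camera adjusted p = 2.3e-05, and adjusted p = 0.046 with an estimated correlation). Of 31 proteasome subunits, 28 rose (30 adjusted over the list alone) and 3 did not pass, with Psmd14 up 2.58-fold and Psmd8 up 2.43-fold. Their median was 0.88 (camera adjusted p = 7.6e-13, but adjusted p = 0.14 with an estimated correlation). Of 17 ubiquitin ligase and FoxO atrophy genes, 7 rose (7 adjusted over the list alone) and 10 did not pass. Their median was 0.33 (camera adjusted p = 0.015, but adjusted p = 0.14 with an estimated correlation). Fbxo32, a muscle ubiquitin ligase, rose 3.66-fold, and the translation repressor Eif4ebp1 and the metallothionein Mt2, which are not ligases, rose 4.30-fold and 4.17-fold. Of 26 autophagy and lysosome genes, 9 rose (11 adjusted over the list alone), 2 fell and 15 did not pass, with Gabarapl1 up 4.18-fold and the protease gene Ctsl up 2.59-fold. Their median was 0.32 (camera adjusted p = 0.014, but adjusted p = 0.057 with an estimated correlation). Of 17 unfolded protein and integrated stress response genes, 10 rose (10 adjusted over the list alone), 2 fell and 5 did not pass, with Atf3 up 10.7-fold and Xbp1 up 3.53-fold. Their median was 0.57 (camera adjusted p = 0.0033, but adjusted p = 0.14 with an estimated correlation).

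Genes of energy metabolism fell relative to the median of all genes. Of 50 respiratory chain and citrate cycle genes, 43 fell (47 adjusted over the list alone) and 7 did not pass, with Mdh1 2.54-fold and Cs, citrate synthase, 2.15-fold lower. Their median was -0.71, or 0.12 with spike-in centring (camera adjusted p = 1.2e-15, but adjusted p = 0.14 with an estimated correlation). Of 18 glycolysis and glycogen genes, 15 fell (16 adjusted over the list alone), 1 rose and 2 did not pass, with Gpd1 6.92-fold and Tpi1 4.93-fold lower. Their median was -1.12 (camera adjusted p = 1.1e-09, and adjusted p = 0.041 with an estimated correlation). Of 23 fatty acid oxidation genes, 18 fell (20 adjusted over the list alone) and 5 did not pass, with Ppara, a lipid-sensing transcription factor, 6.62-fold lower. Their median was -0.76, or 0.07 with spike-in centring (camera adjusted p = 9.5e-10, but adjusted p = 0.057 with an estimated correlation). Of 24 ion channel and excitation-contraction coupling genes, 17 fell (17 adjusted over the list alone), 4 rose (5 adjusted over the list alone) and 3 did not pass, with Kcna7 8.91-fold and Atp1b1, a sodium pump subunit, 5.36-fold lower. Their median was -0.78, or 0.05 with spike-in centring (camera adjusted p = 4.6e-05, but adjusted p = 0.053 with an estimated correlation).

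Of 14 fast-fibre genes, 13 fell (14 adjusted over the list alone) and 1 did not pass, with Myh2, a fast oxidative myosin heavy chain, 2.58-fold and Casq1 2.02-fold lower. Their median was -0.47, or 0.36 with spike-in centring (camera adjusted p = 2.3e-05, but adjusted p = 0.27 with an estimated correlation). Of 10 slow-fibre genes, 4 rose (4 adjusted over the list alone), 3 fell and 3 did not pass (median 0.15, mean -0.15, camera adjusted p = 0.65). Of 28 Z-disc, M-line and cytoskeletal sarcomere genes, 15 fell (15 adjusted over the list alone), 6 rose (8 adjusted over the list alone) and 7 did not pass. Their median was -0.43, or 0.40 with spike-in centring (camera adjusted p = 0.019, but adjusted p = 0.31 with an estimated correlation). That call ended without denervated control 3 (camera adjusted p = 0.05), with quantile normalization (camera adjusted p = 0.56) and with spike-in centring (camera adjusted p = 0.28). The fast-fibre call ended with quantile normalization (camera adjusted p = 0.059). Of 8 developmental and cardiac sarcomere genes, 4 rose (4 adjusted over the list alone), 1 fell (2 adjusted over the list alone) and 3 did not pass (median 1.45, camera adjusted p = 0.064). This list passed with the replicate block (camera adjusted p = 0.047), with the 5'-to-3' covariate (camera adjusted p = 0.048), without denervated control 2 (camera adjusted p = 0.044) and without innervated control 3 (median 1.99, camera adjusted p = 0.016). Ankrd1, a stress-induced sarcomere protein, rose 49.1-fold and Myh3, the embryonic myosin heavy chain, 10.9-fold, while Actc1, cardiac actin, was 6.82-fold lower.

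Markers of other cells moved as well. Of 24 macrophage and leukocyte markers, 12 rose (14 adjusted over the list alone) and 12 did not pass, with Lgals3 up 14.9-fold and Cd68 up 14.8-fold. Their median was 0.83 (camera adjusted p = 4.1e-05, but adjusted p = 0.24 with an estimated correlation). Of 23 cell cycle genes, 14 rose (16 adjusted over the list alone) and 9 did not pass, led by Rrm2, a subunit of ribonucleotide reductase, up 12.3-fold. Their median was 1.18 (camera adjusted p = 4.3e-06, but adjusted p = 0.057 with an estimated correlation). Of 14 satellite cell and myoblast genes, 7 rose (7 adjusted over the list alone), 1 fell and 6 did not pass, with Tnfrsf12a up 14.8-fold and Mymk, the fusion protein of myoblasts, up 6.34-fold. Their median was 0.59 (camera adjusted p = 0.011, but adjusted p = 0.057 with an estimated correlation). Of 13 endothelial markers, 8 fell (10 adjusted over the list alone) and 5 did not pass, with Pecam1 1.96-fold lower. Their median was -0.58, or 0.25 with spike-in centring (camera adjusted p = 0.00082, and adjusted p = 0.046 with an estimated correlation). The other lists did not pass. Schwann cell and nerve markers had 1 rise and 2 falls among 10 (median -0.36, camera adjusted p = 0.27), with Ngfr, a neurotrophin receptor, up 4.23-fold and Mbp, a myelin protein, 4.78-fold lower on its brightest probe set but higher on its 2 others (1.05 and 0.57). Extracellular matrix and fibroblast genes had 6 rises and 4 falls among 25 (median -0.12, mean 0.13, camera adjusted p = 0.79), p53 target and growth arrest genes 4 rises and 3 falls among 13 (median -0.13, mean 0.20, camera adjusted p = 0.78) and adipocyte markers 1 fall among 5 (median 0.19, camera adjusted p = 0.99). Adjusted over the list alone there were 3, 6 and 4 falls of Schwann cell, extracellular matrix and p53 genes, with the other counts unchanged. With spike-in centring the Schwann cell list passed (median 0.47, against 0.82 for all genes, camera adjusted p = 0.037). Too few members were tested for a set test of the granulocyte list, of which S100a8 rose 44.8-fold while S100a9 changed by 1.14 (limma adjusted p = 0.425), of the erythroid list (Alas2 -0.47, limma adjusted p = 0.247) and of the RUNX list, where Cbfb, the partner of RUNX proteins, changed by 0.14 (limma adjusted p = 0.547).

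Scaling set the zero of these changes. The hybridisation spike-in RNAs averaged 13.37 (log2 signal) on the denervated and 14.02 on the innervated arrays, a difference of -0.65 (exact two-sided permutation test over 462 splits, p = 0.00433). Centring the arrays on them, an alternative added after the data were seen, moved the median of all genes from -0.01 to 0.82 in control muscle and called 15569 probe sets, 14851 up and 718 down. It ended the calls of Casq1, Myh2, Cs and Pecam1 named above (limma adjusted p from 0.161 to 0.528). The spiked RNAs used for the 5'-to-3' ratio also read lower on the denervated arrays. They read 10.924 to 11.337 (log2 signal) there and 11.412 to 11.549 on the innervated arrays. Centring on these RNAs was not tried. Median scaling moved the median of all genes to 0.07, with 4180 of 7081 called probe sets up. List values above are therefore relative to a median of all genes near 0, and a list whose sign turns with spike-in centring still lay below that median, with the respiratory list at -0.71 relative to it, a difference that no factor per array can change. Deviations from the group mean correlated between denervated and innervated control arrays of equal number (r = 0.11, 0.22 and 0.30 across probe sets), so the replicate number was tried as a block. With it in all arrays the count in control muscle was 7515, and 8312 with the block in the 6 control arrays alone. Without denervated control 3 it was 6868.

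In mutant muscle 6894 probe sets changed with denervation, 3416 up and 3478 down, or 3722 genes (limma, n = 2 innervated and 3 denervated arrays). Nrcam rose 205-fold (log2 change 7.68 ± 0.57 SE), Plet1, a surface protein, 181-fold, Orm2, an acute-phase plasma protein, 176-fold, and Chrna9, an acetylcholine receptor subunit, 110-fold. Gdf5 rose 91.3-fold, Myog 57.8-fold, S100a8, a granulocyte calcium-binding protein, 56.8-fold and Blnk, an adaptor of B cell receptor signalling, 48.3-fold (log2 change 5.59 ± 0.14 SE). Perm1 was 143-fold lower (log2 change -7.16 ± 0.27 SE), Smco1 77.7-fold, Kcng4 49.0-fold, Kcnc1 36.4-fold, Ky 23.6-fold and Fn3k 21.7-fold lower. The limma adjusted p of these genes lay at or below 0.000141, and apart from Myog, Blnk and Ky their lower group mean lay within the range of the trp control probe sets.

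The response shared much with that of control muscle. Of the probe sets called, 2529 were higher in both genotypes, where 508 would be by chance, 2470 were lower in both, where 502.1 would be, and 13 changed in opposite directions, where 1010.4 would be. The log2 changes correlated across the 26170 probe sets, which are not independent replicates (Pearson r = 0.776, Spearman rho = 0.729). The log2 changes of the genotypes share no arrays, but their calls share 1 variance per probe set, fitted to all 11 arrays. The calls are therefore not independent, as the numbers by chance assume. Without the filter on dim probe sets Pearson r was 0.51. Leaving out innervated mutant 1 or 2 left 4595 or 4337 probe sets, and without denervated control 3 there were 6860. Spike-in centring moved the median of all genes to 0.46 (6969 up and 1017 down) and median scaling to 0.29 (5750 up and 1644 down).

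By list, receptor and synapse genes had 9 rises (9 adjusted over the list alone) and 3 falls among 15, with Chrna1 up 19.1-fold, Chrnd 19.3-fold and Musk, the kinase that organises the synapse, 6.17-fold. Their median was 1.29 (camera adjusted p = 0.00091, and adjusted p = 0.037 with an estimated correlation). Denervation-responsive genes had 11 rises (12 adjusted over the list alone) and 3 falls among 16, with Hdac4, a histone deacetylase, up 11.6-fold. Their median was 1.35 (camera adjusted p = 2.1e-05, and adjusted p = 0.037 with an estimated correlation). Of 31 proteasome subunits 29 rose (30 adjusted over the list alone). Their median was 0.91 (camera adjusted p = 8.5e-13, but adjusted p = 0.13 with an estimated correlation). Of 17 ubiquitin ligase and FoxO atrophy genes 9 rose (10 adjusted over the list alone), with Fbxo32 up 5.74-fold. Their median was 0.64 (camera adjusted p = 0.00011, and adjusted p = 0.037 with an estimated correlation). Of 26 autophagy and lysosome genes 9 rose (10 adjusted over the list alone) and 1 fell. Their median was 0.32 (camera adjusted p = 0.0025, and adjusted p = 0.037 with an estimated correlation). Of 17 stress response genes 8 rose (10 adjusted over the list alone) and 2 fell. Their median was 0.48 (camera adjusted p = 0.0052, but adjusted p = 0.16 with an estimated correlation). Of 24 macrophage and leukocyte markers 20 rose (22 adjusted over the list alone), with Cd68 up 29.2-fold and Ptprc, the leukocyte common antigen, 3.29-fold. Their median was 1.39 (camera adjusted p = 1.5e-10, but adjusted p = 0.091 with an estimated correlation). Of 23 cell cycle genes 12 rose (16 adjusted over the list alone, with 1 fall), with Mki67 up 12.3-fold. Their median was 1.03 (camera adjusted p = 1.9e-05, but adjusted p = 0.064 with an estimated correlation).

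Among lists that fell in mutant muscle, respiratory chain and citrate cycle genes had 38 falls among 50 (38 adjusted over the list alone). Their median was -0.67 (camera adjusted p = 3.9e-15, but adjusted p = 0.14 with an estimated correlation). Glycolysis and glycogen genes had 15 falls (15 adjusted over the list alone) and 1 rise among 18. Their median was -1.10 (camera adjusted p = 1.9e-09, and adjusted p = 0.037 with an estimated correlation). Fatty acid oxidation genes had 15 falls among 23 (18 adjusted over the list alone). Their median was -0.60 (camera adjusted p = 2.1e-07, but adjusted p = 0.091 with an estimated correlation). Ion channel and excitation-contraction coupling genes had 16 falls (16 adjusted over the list alone) and 4 rises (5 adjusted over the list alone) among 24. Their median was -0.88 (camera adjusted p = 1.7e-05, and adjusted p = 0.037 with an estimated correlation). Fast-fibre genes had 13 falls among 14 (14 adjusted over the list alone), with Myh2 13.7-fold lower. Their median was -0.59 (camera adjusted p = 5.5e-07, but adjusted p = 0.19 with an estimated correlation). Z-disc, M-line and cytoskeletal genes had 15 falls (15 adjusted over the list alone) and 3 rises among 28. Their median was -0.55 (camera adjusted p = 0.00012, but adjusted p = 0.13 with an estimated correlation). Endothelial markers had 5 falls among 13 (6 adjusted over the list alone). Their median was -0.51 (camera adjusted p = 0.004, and adjusted p = 0.048 with an estimated correlation). Leaving out innervated mutant 1 ended the calls of Pecam1, Ptprb and Tie1 among these, with limma adjusted p of 0.133, 0.21 and 0.135, and some other single arrays did so too.

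No set test passed for the remaining lists in mutant muscle. Developmental and cardiac sarcomere genes had 3 rises and 2 falls among 8 (median -0.66, camera adjusted p = 0.9), slow-fibre genes 1 rise and 1 fall among 10 (median -0.35, camera adjusted p = 0.61), and satellite cell and myoblast genes 3 rises and 2 falls among 14 (median 0.09, camera adjusted p = 0.35). Extracellular matrix and fibroblast genes had 1 rise and 9 falls among 25 (median -0.43, camera adjusted p = 0.051), Schwann cell and nerve markers 2 rises and 3 falls among 10 (median -0.41, camera adjusted p = 0.24), p53 targets 4 rises and 3 falls among 13 (median 0.03, camera adjusted p = 0.61) and adipocyte markers no calls among 5 (median -0.50, camera adjusted p = 0.25). Adjusted over the list alone there were 3 falls of developmental, 2 of slow-fibre, 10 of extracellular matrix, 4 of Schwann cell and 4 of p53 genes and 4 rises of satellite cell genes, with the other counts unchanged. The extracellular matrix list passed with quantile normalization (camera adjusted p = 0.041) and when any 1 of 7 arrays was left out, with the lowest camera adjusted p = 0.0098 without denervated mutant 1 (median -0.55). S100a9 changed by 2.1 (limma adjusted p = 0.175), Alas2 by -0.80 (limma adjusted p = 0.0859) and Cbfb by 0.19 (limma adjusted p = 0.436).

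**Figure D1:**
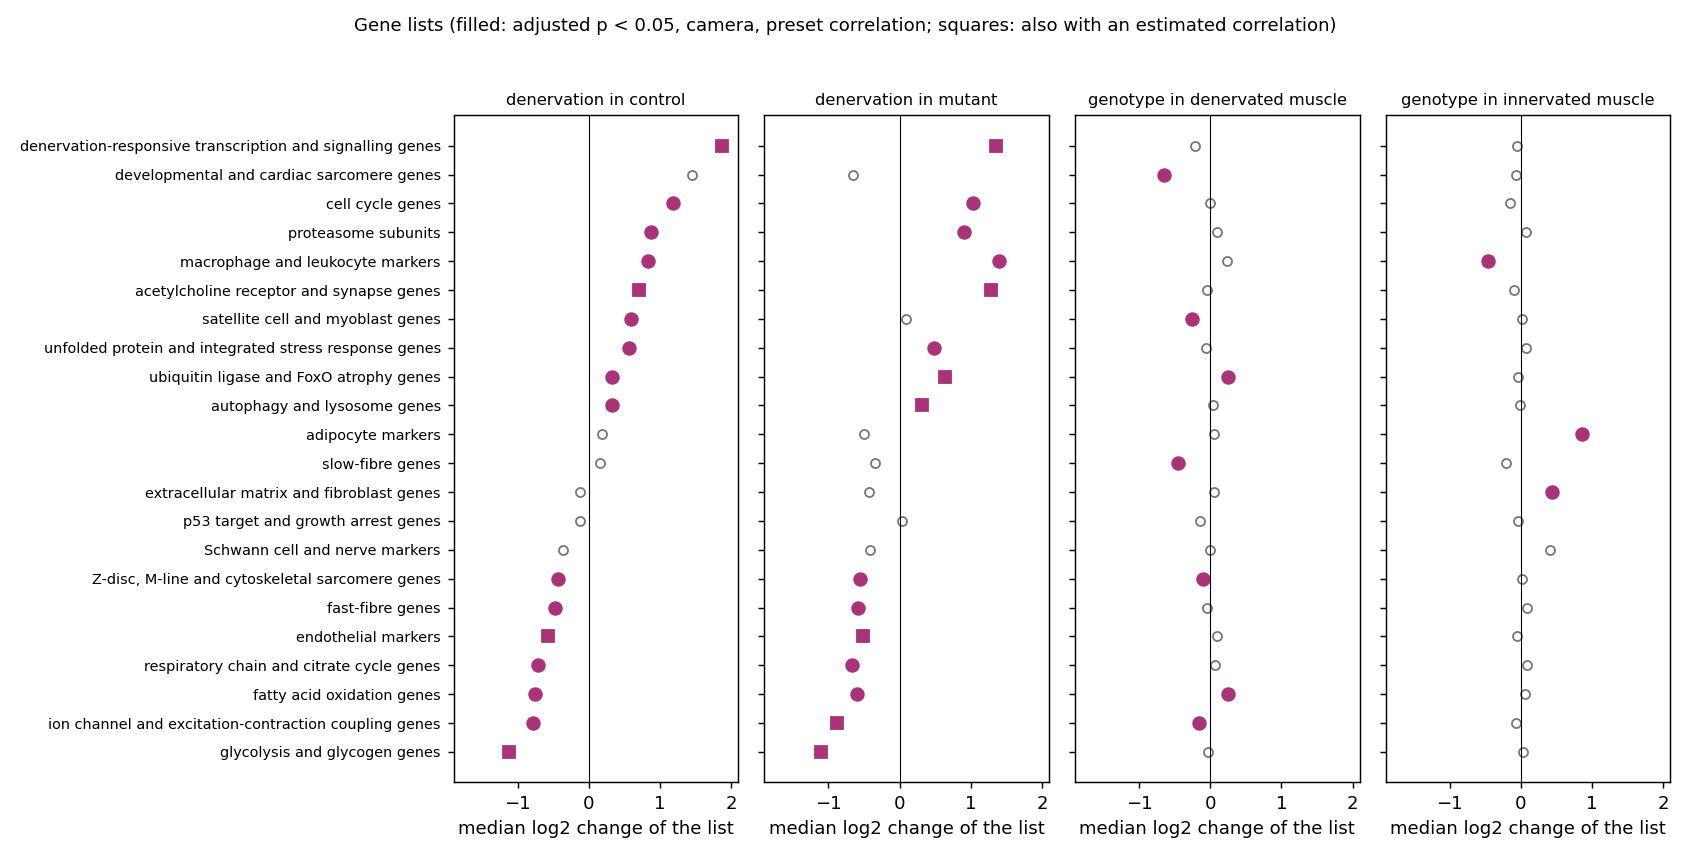
Median log2 change of each gene list (x axes) in each of 4 comparisons (panels), lists ordered by denervation in control muscle; filled symbols passed with the preset correlation and squares also with an estimated one. Proteasome subunits lie at 0.88 and 0.91 and glycolysis genes at -1.12 and -1.10 with denervation in control and mutant muscle; with spike-in centring the fast-fibre, Z-disc, ion channel, respiratory, fatty acid oxidation and endothelial medians of control muscle turn positive, the ubiquitin ligase and fatty acid oxidation medians of the genotype comparison turn negative, and with median scaling the Z-disc median of that comparison is 0.

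Mutant and control muscle differed clearly once denervated. Chrng was 17.6-fold lower than in denervated control muscle (log2 difference -4.14 ± 0.30 SE, n = 3 and 3, limma adjusted p = 2.21e-05), Myh3 20.9-fold lower (-4.38 ± 0.31 SE, limma adjusted p = 1.74e-05) and Mymk 10.6-fold lower (-3.40 ± 0.50 SE, limma adjusted p = 0.00315). Rrad was 21.1-fold lower (-4.40 ± 0.59 SE, limma adjusted p = 0.00196), Krt8 9.37-fold, Aif1l, an actin-bundling protein, 8.84-fold, Rrm2 7.83-fold, Myh2 6.85-fold, Sh3rf1, a scaffold of stress kinase signalling, 6.59-fold and Nptx1, a neuronal pentraxin, 6.50-fold lower. Lcn2, a siderophore-binding lipocalin, was 8.96-fold higher (3.16 ± 0.40 SE, limma adjusted p = 0.00125), Orm1 and Orm2, acute-phase proteins, 8.32-fold and 7.31-fold, Sfrp2, a secreted Wnt modulator, 7.49-fold, and Plin5, a lipid droplet protein, 4.34-fold higher. Aqp4 was 6.80-fold, Ripply3, a transcriptional repressor, 5.83-fold, Plet1os, a transcript next to Plet1, 5.37-fold, Prima1, the membrane anchor of acetylcholinesterase, 4.54-fold and Gpnmb, a glycoprotein of macrophages and other cells, 3.85-fold higher. The denervated control mean of Aqp4 lay within the range of the trp control probe sets, so the size of its fold rests on background. In all 478 probe sets differed, 211 higher and 267 lower in the mutant, or 267 genes (limma).

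Many of these genes respond to denervation. Of the 267 probe sets lower in the mutant, 151 had risen with denervation in control muscle, where 39.7 would be by chance, and 55 had fallen, where 38.5 would be; of the 211 higher ones, 84 had fallen, where 30.5 would be, and 52 had risen, where 31.4 would be. Both comparisons use the denervated control arrays, which by itself makes the changes go opposite ways: over all tested probe sets their correlation was -0.232, against -0.501 in 20 simulations without any effect. Their covariance was -0.079 against -0.054 in those simulations, more negative than without an effect. The overlap alone is therefore not independent evidence for or against a weaker response. The log2 level of the hybridisation spike-ins was 0.38 higher on the denervated mutant than on the denervated control arrays (exact two-sided permutation test, p = 0.1, the smallest possible). The spiked RNAs used for the 5'-to-3' ratio overlapped, at 10.928 to 11.117 (log2 signal) on the denervated mutant and 10.924 to 11.337 on the denervated control arrays.

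By list, 1 of 8 developmental and cardiac sarcomere genes was lower (5 adjusted over the list alone), the passing member being Myh3. Their median was -0.65 (camera adjusted p = 6.9e-06, but adjusted p = 0.15 with an estimated correlation). Of 10 slow-fibre genes 2 were lower (4 adjusted over the list alone): the slow troponins Tnni1, 4.31-fold, and Tnnt1, 2.83-fold. Their median was -0.45 (camera adjusted p = 0.00024, but adjusted p = 0.16 with an estimated correlation). Of 28 Z-disc, M-line and cytoskeletal sarcomere genes 5 were lower (6 adjusted over the list alone), among them Xirp1, 3.29-fold, Lmod2, an actin nucleator, 2.46-fold, Myot 1.63-fold and Fhl1 1.61-fold. Their median was -0.10, or 0 with median scaling (camera adjusted p = 0.00024, but adjusted p = 0.22 with an estimated correlation). Of 14 satellite cell and myoblast genes 2 were lower (5 adjusted over the list alone, with 1 higher): Mymk, and Itga7, a laminin-binding integrin, 2.45-fold. Their median was -0.26 (camera adjusted p = 0.009, but adjusted p = 0.15 with an estimated correlation). Of 24 ion channel and excitation-contraction coupling genes 2 were lower and 1 higher (8 and 3 adjusted over the list alone): Rrad and the potassium channel gene Kcnq5 (1.85-fold) were lower and Atp1b1 (1.79-fold) higher. Their median was -0.16 (camera adjusted p = 0.016, but adjusted p = 0.22 with an estimated correlation). Of 23 fatty acid oxidation genes 2 were higher (4 adjusted over the list alone): Ppara, 2.50-fold, and Lpl, lipoprotein lipase, 1.46-fold. Their median was 0.25, or -0.13 with spike-in centring (camera adjusted p = 0.00024, but adjusted p = 0.33 with an estimated correlation). Of 17 ubiquitin ligase and FoxO atrophy genes 1 was higher (3 adjusted over the list alone): Fbxo31, 2.00-fold. Their median was 0.25, or -0.13 with spike-in centring (camera adjusted p = 0.026, but adjusted p = 0.22 with an estimated correlation). Leaving out denervated mutant 1 ended the calls of the ubiquitin ligase list (camera adjusted p = 0.056) and the ion channel list (camera adjusted p = 0.08), and the former also ended with quantile normalization (camera adjusted p = 0.051) and without camera's trend (camera adjusted p = 0.054).

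No member of several large lists passed over all tested probe sets or over the list alone between genotypes in denervated muscle: 0 of 31 proteasome subunits (median 0.09, camera adjusted p = 0.24), 0 of 26 autophagy and lysosome genes (median 0.04, camera adjusted p = 0.42), 0 of 50 respiratory chain and citrate cycle genes (median 0.06, camera adjusted p = 0.28) and 0 of 17 stress response genes (median -0.06, camera adjusted p = 0.3). No call was made either way among 24 macrophage and leukocyte markers (median 0.23, camera adjusted p = 0.13), 25 extracellular matrix and fibroblast genes (median 0.05, mean -0.01, camera adjusted p = 0.81), 13 endothelial markers (median 0.10, camera adjusted p = 0.29), 10 Schwann cell and nerve markers (median 0.00, camera adjusted p = 0.57) and 5 adipocyte markers (median 0.05, camera adjusted p = 0.83). Of 18 glycolysis and glycogen genes none passed over all tested probe sets, and 2 were higher and 1 lower adjusted over the list alone (median -0.03, mean 0.04, camera adjusted p = 0.76). Chrng was the only call over all tested probe sets among 15 receptor and synapse genes, with 2 higher and 3 lower adjusted over the list alone (median -0.05, camera adjusted p = 0.23). Either way the only call was Hdac4, 1.79-fold higher, among 16 denervation-responsive genes (median -0.22, camera adjusted p = 0.29), Myh2 among 14 fast-fibre genes (median -0.04, camera adjusted p = 0.25) and Rrm2 among 23 cell cycle genes (median 0.00, mean -0.18, camera adjusted p = 0.25). Of 13 p53 targets Trp53inp1 was 2.11-fold higher and Sesn1 1.90-fold lower, with 2 higher and 3 lower adjusted over the list alone (median -0.15, camera adjusted p = 0.25). Several of these lists passed when 1 array was left out. Without denervated control 3 the fast-fibre list did (median -0.15, camera adjusted p = 0.0032), and so did the stress response list (median -0.22, camera adjusted p = 0.039). Without denervated mutant 3 the fast-fibre list (camera adjusted p = 0.031), the macrophage list (median 0.26, camera adjusted p = 0.031) and the extracellular matrix list (median 0.18, camera adjusted p = 0.027) did. The macrophage list also passed without denervated control 1 (median 0.30, camera adjusted p = 0.014) or denervated mutant 1 (median 0.29, camera adjusted p = 0.014). With spike-in centring the fast-fibre list (median -0.42, camera adjusted p = 0.022) and the macrophage list (median -0.15, camera adjusted p = 0.037) passed, against a median of all genes of -0.37. S100a8 differed by 1.07 (limma adjusted p = 0.11), S100a9 by 2.16 (limma adjusted p = 0.424), Alas2 by 0.12 (limma adjusted p = 0.936) and Cbfb by 0.15 (limma adjusted p = 0.802). In simulated data of this comparison, with 200 of 26170 probe sets changed, 42% of changes of 1 log2 unit were recovered. Of changes of 2 log2 units 85% were recovered.

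Of the 35 genes named by the rule that passed here, 25 passed under every alternative with the same probe set; Orm1, Nptx1, Hdac4, Fbxo31, Fhl1, Atp1b1, Kcnq5, Lpl, Trp53inp1 and Sesn1 lost the call under at least 1, each without at least 2 of the single arrays, and with limma adjusted p of up to 0.214 for Lpl, 0.182 for Sesn1, 0.162 for Orm1 and 0.119 for Nptx1. Of 32 values from other probe sets of the 35 genes, 22 passed in the same direction and 10 did not pass. The count of called probe sets fell to 223 and 271 without denervated control 1 and 2, and was 471 without denervated control 3 (238 higher and 233 lower). It fell to 278, 245 and 247 without denervated mutant 1, 2 and 3. Median scaling gave 227 higher and 180 lower probe sets with the median of all genes at 0.11, and spike-in centring 54 higher and 1342 lower with that median at -0.37.

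**Figure D2:**
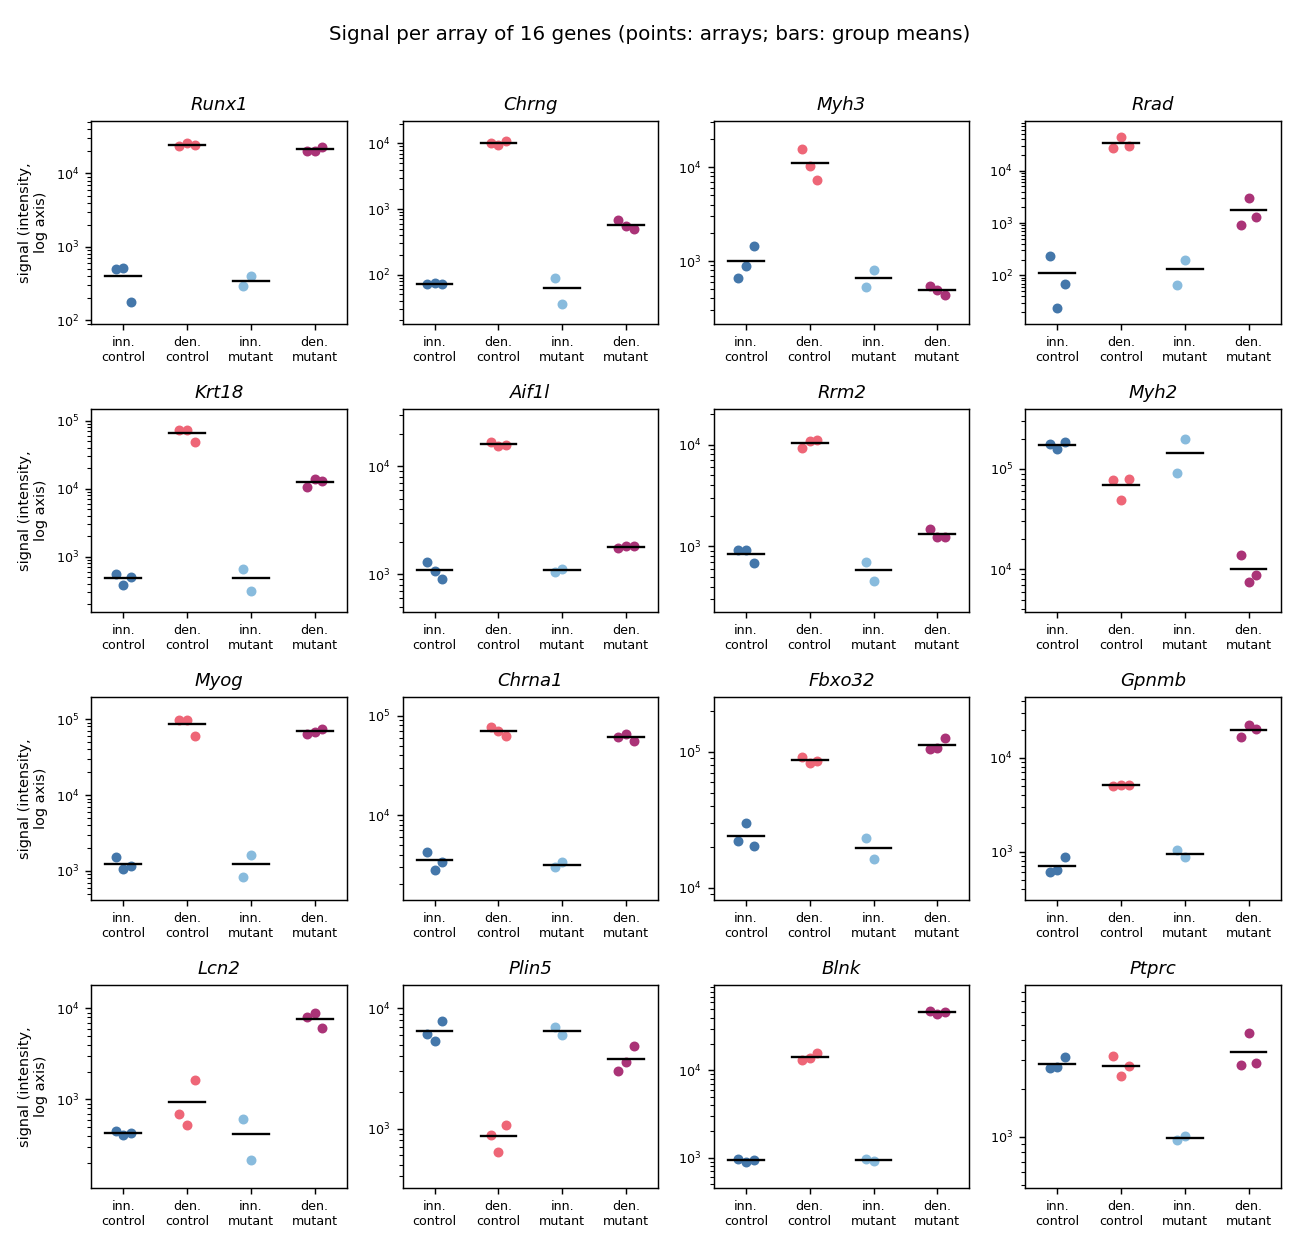
Signal of 16 genes on each of the 11 arrays (points, intensity on a log axis) by group, with bars at the group means. Chrng, Myh3 and Rrad are high in denervated control muscle (means of 10285, 10983 and 33597) and far lower in denervated mutant muscle (574, 489 and 1740), while Runx1 is high in both (24583 and 21346).

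In innervated muscle no probe set differed between genotypes (limma, 0 of 26170, with 1030 at an unadjusted p under 0.05 and a smallest adjusted p of 0.15, n = 2 mutant and 3 control arrays). The 5 genes with the smallest p were all lower in the mutant without passing. They were Ptprc (log2 difference -1.51 ± 0.21 SE, limma adjusted p = 0.15), Itgb2, a leukocyte integrin (-1.64 ± 0.25 SE, limma adjusted p = 0.17), Selplg, a selectin ligand (-1.91 ± 0.37 SE, limma adjusted p = 0.503), Sla, an adaptor protein (-1.66 ± 0.33 SE, limma adjusted p = 0.503), and Gfap, a glial filament (-2.01 ± 0.37 SE, limma adjusted p = 0.42). As a set, 24 macrophage and leukocyte markers were lower in the mutant (median -0.46, camera adjusted p = 1.7e-10, but adjusted p = 0.6 with an estimated correlation), with 0 members past the test and 3 adjusted over the list alone. The 25 extracellular matrix and fibroblast genes were higher as a set (median 0.44, camera adjusted p = 1.7e-10, but adjusted p = 0.6 with an estimated correlation) with 0 members past the test either way, and so were 5 adipocyte markers (median 0.86, camera adjusted p = 0.0056, but adjusted p = 0.6 with an estimated correlation), a call that ended without innervated mutant 1 or innervated control 1 (camera adjusted p up to 0.21).

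The other 19 tested lists did not pass in innervated muscle, and no member of any list passed over all tested probe sets. Adjusted over the list alone, 1 cell cycle gene and 1 Schwann cell marker were lower, besides the 3 macrophage markers. Their medians were -0.10 for receptor and synapse genes (camera adjusted p = 0.84), -0.06 for denervation-responsive genes (camera adjusted p = 0.97), -0.04 for ubiquitin ligase genes (camera adjusted p = 0.21), 0.07 for proteasome subunits (camera adjusted p = 0.36), -0.02 for autophagy genes (camera adjusted p = 0.87), -0.07 for developmental sarcomere genes (mean 0.05, camera adjusted p = 1), 0.08 for fast-fibre genes (camera adjusted p = 0.32) and -0.21 for slow-fibre genes (camera adjusted p = 0.27). They were 0.02 for Z-disc genes (camera adjusted p = 1), -0.07 for ion channel genes (camera adjusted p = 0.32), 0.03 for glycolysis genes (camera adjusted p = 0.97), 0.08 for respiratory genes (camera adjusted p = 0.21), 0.06 for fatty acid oxidation genes (camera adjusted p = 0.97) and -0.16 for cell cycle genes (camera adjusted p = 0.32). They were 0.02 for satellite cell genes (camera adjusted p = 0.97), 0.41 for Schwann cell markers (camera adjusted p = 0.32), -0.05 for endothelial markers (camera adjusted p = 1), -0.04 for p53 targets (camera adjusted p = 0.83) and 0.07 for stress response genes (mean -0.03, camera adjusted p = 1). Some of these calls turned on single arrays. The respiratory list passed as higher without innervated mutant 1 (median 0.26, camera adjusted p = 3.2e-06) and as lower without innervated mutant 2 (median -0.09, camera adjusted p = 0.005). As higher it also passed without innervated control 1 or 3, with the replicate block (camera adjusted p = 0.045) and with the 5'-to-3' covariate (camera adjusted p = 0.022). The proteasome list passed as lower without innervated control 2 (median -0.10, camera adjusted p = 0.029), and as higher without innervated control 3 (median 0.16, camera adjusted p = 0.0074) or 1 and with the covariate (camera adjusted p = 0.046 for each). The cell cycle list passed without innervated mutant 2 (median -0.24, camera adjusted p = 0.0019) and the ubiquitin ligase list without innervated control 3 (median -0.12, camera adjusted p = 0.048). S100a8 differed by 0.72, S100a9 by 1.2, Alas2 by 0.44 and Cbfb by 0.10 (limma adjusted p = 0.998 for each). Leaving out innervated mutant 1 or 2 called 12 or 3 probe sets, limma without trend called 3 and the 5'-to-3' covariate 2. In simulated data of this comparison, with 200 of 26170 probe sets changed, 23% of changes of 1 log2 unit were recovered. Of changes of 2 log2 units 77% were recovered.

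**Figure D3:**
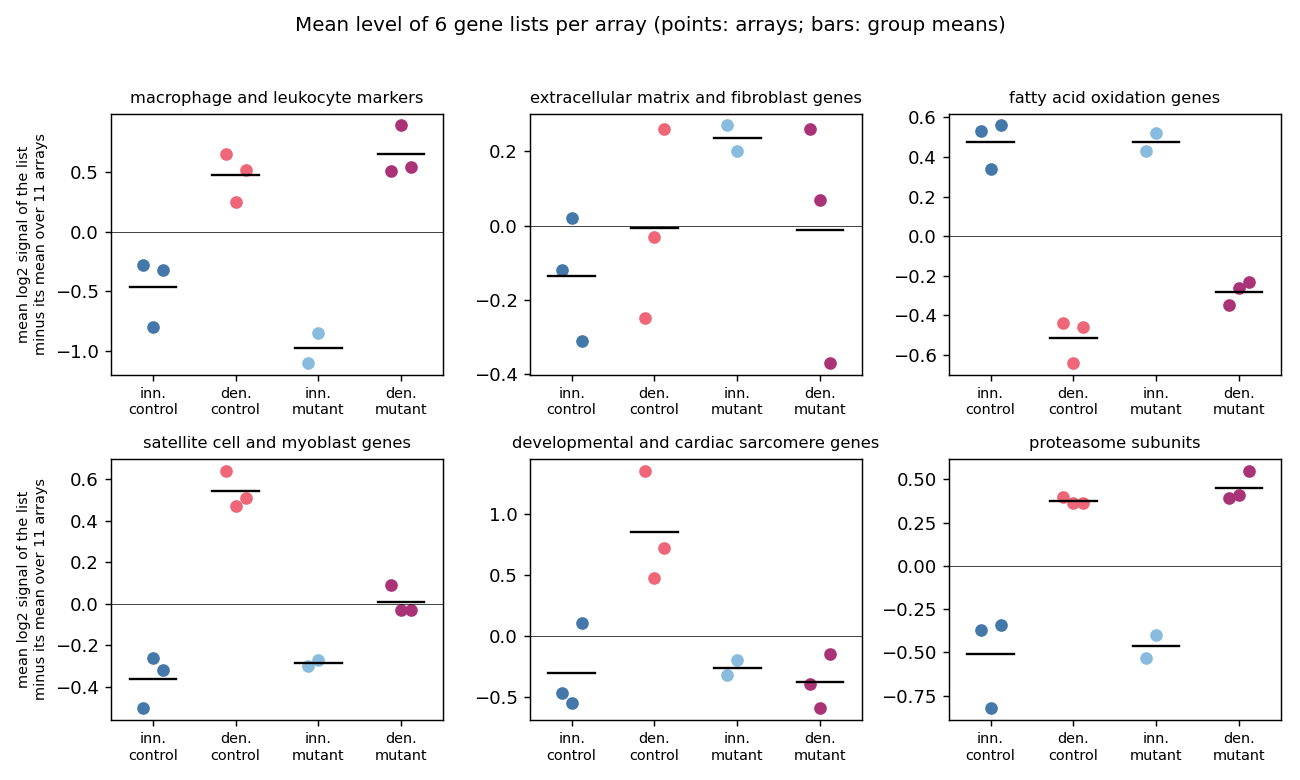
Mean log2 signal of 6 gene lists on each of the 11 arrays (points), as the difference from the mean over all arrays, by group, with bars at the group means. Macrophage and leukocyte markers are lowest in the innervated mutant arrays, and fatty acid oxidation genes lie lower in denervated control than in denervated mutant muscle, a median difference of 0.25 that is -0.13 with spike-in centring.

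The interaction tested whether the denervation response differed between genotypes. The response of Chrng differed by -3.87 ± 0.46 (SE, log2, all 11 arrays, limma adjusted p = 0.00603), that of Myh3 by -3.86 ± 0.46 (limma adjusted p = 0.00603), that of Aif1l by -3.16 ± 0.23 (limma adjusted p = 0.000118) and that of Rrm2 by -2.42 ± 0.30 (limma adjusted p = 0.00605). Rrad (-4.89), Sh3rf1 (-3.44), Enpp3, an ectonucleotidase (-2.71), Pln, the phospholamban that restrains the calcium pump (-2.69), Myh2 (-2.41) and Krt18 (-2.31) also responded less or fell further in the mutant. The innervated signals of Chrng (35.7 to 89.4) and Rrad (23.9 to 236.2) lay within the range of the trp control probe sets. The size of these 2 interactions therefore rests partly on background. The response was more positive in the mutant for Lcn2 (3.39), Ripply3 (3.08), Plet1os (2.73), Aqp4 (2.65), the lipid droplet genes Plin5 (2.09) and Plin4 (1.86), Ppara (1.84) and Blnk (1.70). Itgb2 (2.04) and Ptprc (1.76) passed as well, but their difference rests on low values of innervated mutant muscle. The signal of Ptprc was 2852 ± 270.1 (SD, n = 3) in innervated and 2781.4 ± 400.2 (SD, n = 3) in denervated control muscle, and 989.6 ± 40.2 (SD, n = 2) and 3368.9 ± 912.2 (SD, n = 3) in the mutant. That of Itgb2 was 1178.5 ± 173.1 and 1382 ± 257 (SD, n = 3 each) in control muscle and 363.8 ± 11.7 (SD, n = 2) and 1848.8 ± 484.1 (SD, n = 3) in the mutant. Plin4, for example, fell from 39773 ± 3462 (SD, n = 3) to 8229 ± 1576 (SD, n = 3) in control muscle and stood at 30313 ± 6588 (SD, n = 2) and 22572 ± 3998 (SD, n = 3) in the mutant. In all 65 probe sets passed, 22 more positive and 43 more negative in the mutant, or 32 genes (limma, 2017 at an unadjusted p under 0.05).

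By list, the response was more negative in the mutant for developmental and cardiac sarcomere genes (1 of 8 past the test, 1 adjusted over the list alone; median -0.83, camera adjusted p = 2.4e-05, but adjusted p = 0.16 with an estimated correlation) and for satellite cell and myoblast genes (0 of 14, 2 adjusted over the list alone; median -0.51, camera adjusted p = 0.0065, but adjusted p = 0.16 with an estimated correlation). It was also more negative for Z-disc genes (0 of 28, 5 adjusted over the list alone; median -0.18, or 0.05 with median scaling, camera adjusted p = 0.0012, but adjusted p = 0.38 with an estimated correlation), for slow-fibre genes (0 of 10, 1 adjusted over the list alone; median -0.34, camera adjusted p = 0.028, but adjusted p = 0.4 with an estimated correlation) and for fast-fibre genes (1 of 14, 1 adjusted over the list alone; median -0.10, or 0.12 with median scaling, camera adjusted p = 0.038, but adjusted p = 0.69 with an estimated correlation). Extracellular matrix and fibroblast genes did the same (0 of 25, 1 adjusted over the list alone; median -0.22, or 0.01 with median scaling, camera adjusted p = 0.00052, but adjusted p = 0.52 with an estimated correlation). The response was more positive for macrophage and leukocyte markers (1 of 24, 1 adjusted over the list alone; median 0.77, camera adjusted p = 2.8e-07, but adjusted p = 0.38 with an estimated correlation), ubiquitin ligase and FoxO atrophy genes (0 of 17, 2 adjusted over the list alone; median 0.42, camera adjusted p = 0.003, but adjusted p = 0.16 with an estimated correlation) and fatty acid oxidation genes (1 of 23, 1 adjusted over the list alone; median 0.25, or -0.10 with spike-in centring, camera adjusted p = 0.0063, but adjusted p = 0.52 with an estimated correlation). The macrophage median differed between genotypes by 0.23 in denervated and -0.46 in innervated muscle. The extracellular matrix median differed by 0.05 and 0.44, so much of both interactions lies in the innervated arrays. The call of the fast-fibre list ended in 9 of 18 alternatives. It did when any 1 of 4 arrays was left out (camera adjusted p up to 0.64), with the replicate block (median -0.06, camera adjusted p = 0.14), quantile normalization (camera adjusted p = 0.18), median scaling (camera adjusted p = 0.33) and the 5'-to-3' covariate (camera adjusted p = 0.22), and without camera's trend (camera adjusted p = 0.084). That of the slow-fibre list ended in 7. It did when any 1 of 5 arrays was left out (camera adjusted p up to 0.15), with spike-in centring (camera adjusted p = 0.2) and without camera's trend (camera adjusted p = 0.051). Spike-in centring also ended that of the fatty acid oxidation list (camera adjusted p = 0.069). Leaving out 1 array ended the calls of the ubiquitin ligase list (camera adjusted p = 0.062, without innervated mutant 2), the fatty acid oxidation list (camera adjusted p = 0.093, without innervated mutant 1) and the extracellular matrix list (camera adjusted p = 0.068, without denervated control 3).

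The other 13 lists did not pass the interaction test. Their medians were -0.02 for receptor and synapse genes (camera adjusted p = 0.41), -0.15 for denervation-responsive genes (camera adjusted p = 0.6), 0.03 for proteasome subunits (camera adjusted p = 0.76), 0.09 for autophagy genes (camera adjusted p = 0.41), -0.07 for ion channel genes (camera adjusted p = 0.28), -0.11 for glycolysis genes (mean 0.02, camera adjusted p = 0.96) and -0.01 for respiratory genes (mean 0.01, camera adjusted p = 0.93). They were 0.20 for cell cycle genes (mean -0.04, camera adjusted p = 0.71), -0.09 for Schwann cell markers (camera adjusted p = 0.93), 0.15 for endothelial markers (camera adjusted p = 0.48), -0.69 for adipocyte markers (camera adjusted p = 0.12, against 0.038 with the replicate block and median -0.95), -0.05 for p53 targets (mean 0.01, camera adjusted p = 0.6) and -0.09 for stress response genes (camera adjusted p = 0.5). Adjusted over the list alone, 1 receptor gene was more negative, 1 gene each of the denervation-responsive and p53 lists more positive, and 1 gene each way of the ion channel and cell cycle lists. The adipocyte list also passed with median scaling (camera adjusted p = 0.026), the 5'-to-3' covariate (camera adjusted p = 0.021), and without denervated control 2 (camera adjusted p = 0.022) or denervated mutant 1 (camera adjusted p = 0.017). The respiratory list passed as more negative without innervated mutant 1 (median -0.18, camera adjusted p = 0.0057) and as more positive without innervated mutant 2 (median 0.16, camera adjusted p = 0.0082), and the proteasome list as more positive without innervated control 2 (median 0.21, camera adjusted p = 0.0054). S100a8 had an interaction of 0.34 (limma adjusted p = 0.922), S100a9 of 0.96 (limma adjusted p = 0.935), Alas2 of -0.32 (limma adjusted p = 0.924) and Cbfb of 0.05 (limma adjusted p = 0.98).

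Few single genes held under every alternative of the interaction test: Chrng, Myh3, Aif1l and Rrm2 did, of the 20 named, and Blnk lost its call under 1 alternative, spike-in centring (limma adjusted p = 0.0737). Of 18 values from other probe sets of the 20 genes, 10 passed in the same direction and 8 did not pass. Without the trend limma called 10 probe sets in place of 65. Leaving out 1 array ended calls of 15 of the 20, up to limma adjusted p = 0.221 for Rrad, and the count fell to 16 without innervated mutant 2, 24 without denervated mutant 2, 25 without denervated control 2, 33 without denervated mutant 3, 35 without denervated control 1 and 36 without innervated mutant 1 or innervated control 1, but rose to 108 without innervated control 2 and was 91 without denervated control 3. The lean to negative differences depended on these choices: 46 were more positive and 45 more negative without denervated control 3, 46 and 62 without innervated control 2, and 27 and 26 with one probe set per gene. Median scaling gave 28 more positive and 28 more negative probe sets with the median of all genes at 0.24, and spike-in centring 2 and 75 with that median at -0.34.

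**Figure D4:**
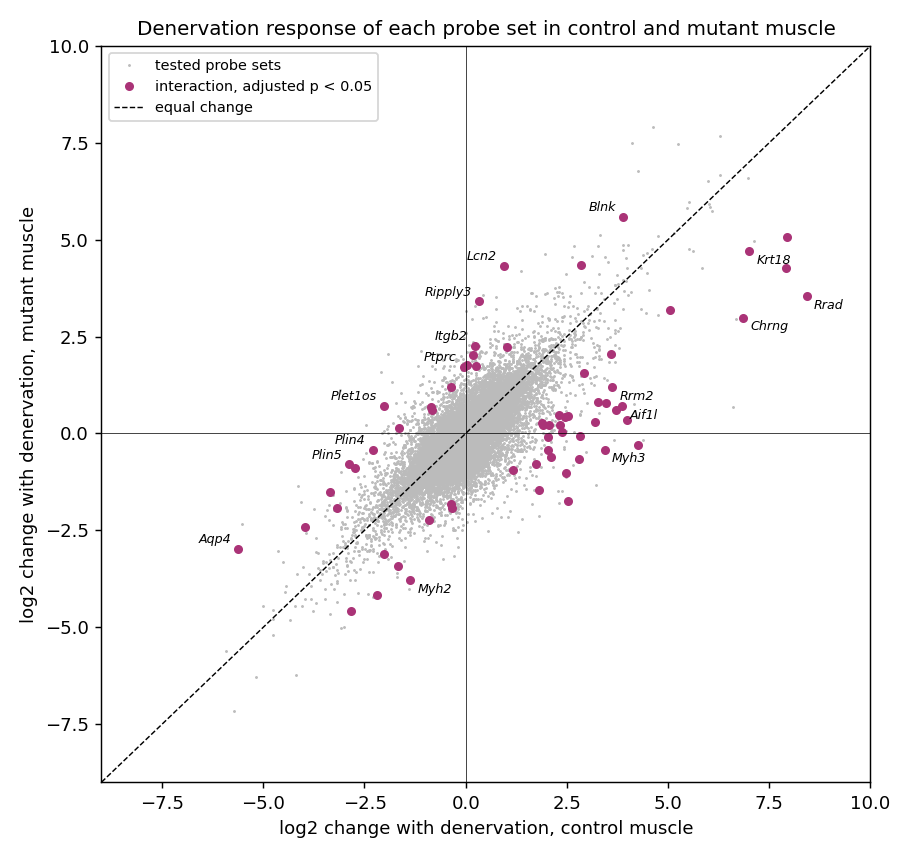
Log2 change with denervation of each of 26170 probe sets in control (x axis) and mutant muscle (y axis), with the 65 probe sets past the interaction test in colour, 16 genes labelled, and a dashed line of equal change. Chrng and Rrad lie far below the line and Blnk and Lcn2 above it, and over all probe sets Pearson r is 0.776.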

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

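The tests of array scaling and of labelling quality in denervated control 3 were chosen after values close to their results had been seen, and centring on the spike-in RNAs and the 5'-to-3' covariate were added after the data were seen.

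The denervation response differed between genotypes for 65 probe sets, by a limma test of the difference between the 2 responses themselves. Responses were more positive in the mutant for Lcn2 (3.39, log2), Ripply3 (3.08), Plet1os (2.73), Aqp4 (2.65), Plin5 (2.09), Itgb2 (2.04), Plin4 (1.86), Ppara (1.84), Ptprc (1.76) and Blnk (1.70). They were more negative for Rrad (-4.89), Chrng (-3.87), Myh3 (-3.86), Sh3rf1 (-3.44), Aif1l (-3.16), Enpp3 (-2.71), Pln (-2.69), Rrm2 (-2.42), Myh2 (-2.41) and Krt18 (-2.31). By list, the median difference was 0.77 for macrophage and leukocyte markers, 0.42 for ubiquitin ligase and FoxO atrophy genes and 0.25 for fatty acid oxidation genes. It was -0.83 for developmental and cardiac sarcomere genes, -0.51 for satellite cell and myoblast genes, -0.34 for slow-fibre genes, -0.22 for extracellular matrix and fibroblast genes, -0.18 for Z-disc, M-line and cytoskeletal sarcomere genes and -0.10 for fast-fibre genes. The differences of Itgb2, Ptprc and the macrophage list rest largely on low values in innervated mutant muscle. These lists passed camera with the preset correlation, and 0 of them with an estimated one.

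In denervated muscle 478 probe sets differed between genotypes. Labelling quality was read from the 5'-to-3' ratio of spiked RNAs. With this ratio as a covariate a median of 99.3% of the log2 difference was left. The ratio itself differed by -0.13 (log2) between denervated mutant and denervated control arrays (exact two-sided permutation test, p = 0.6). A covariate so alike in both groups can remove little of a difference between them, so this test cannot decide on labelling quality. The targeted Runx1 allele is a candidate explanation that the design names. An effect of the MCK::cre transgene itself cannot be told apart from it, since only the mutant carried it. Batch or animal effects shared by a group stay open too, as the labels give neither. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many calls, the real one, and the highest of the others gave 1 call; so few splits cannot give a share under 0.05.

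Denervated control 3 stood apart from the other denervated controls on the second principal component, at -12.2 against 38.2 and 41.7, with the denervated mutant arrays between -24.5 and -16.8. The innervated controls spread more widely on that component, from -38.7 to 40.7. Over all tested probe sets the denervated controls correlated with each other at 0.958 to 0.963, and the innervated controls at 0.943 to 0.964. A mislabelled mutant sample was argued against: over the probe sets called without denervated control 3, its median position was 0.757 on a scale from the mutant mean at 0 to the other controls at 1, where denervated control 1 and 2 gave 1 and 0.948 in the same test. Labelling quality stays open: its deviation correlated at 0.299 with that of innervated control 3, the array with an equally low 5'-to-3' ratio, between the bounds of 0.1 and 0.3 set for the test, and at 0.303 over all tested probe sets. A shared animal or shared handling would give such a correlation too. The treatment note of denervated control 3 gives 5 days of denervation where its title gives 3. Over the probe sets called for denervation without it, its median position was 0.864 from the innervated controls at 0 to the other denervated controls at 1. Denervated control 1 and 2 gave 0.958 and 0.995. Whether 5 days of denervation would give such a position was not tested.

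Denervation of control muscle changed 7670 probe sets about equally in both directions, while the hybridisation spike-in RNAs read -0.65 (log2) on denervated against innervated arrays. Array scaling as the cause of all calls was argued against: at a limma adjusted p under 0.001, 290 probe sets were lower and 1135 higher under all 4 scalings, where that threshold allows 6.7 false calls, and a factor per array moves all probe sets alike. The direction of the smaller changes stays open, among them the respiratory list (camera adjusted p = 0.14 with an estimated correlation), whose median of -0.71 was 0.12 with spike-in centring. That centring used the hybridisation spike-ins alone. The spiked RNAs of the 5'-to-3' ratio read lower on denervated arrays too, but centring on them was not tried. Of the 10 splits of the 6 control arrays, 1 gave as many calls, the real one, and the highest of the others gave 0; so few splits cannot give a share under 0.05. The loss of the nerve is the biological explanation that the design names.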

How the results depend on the processing

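Alternatives chosen after the data were seen were a larger pseudocount, spike-in centring, the 5'-to-3' covariate, the block in the control arrays alone, and for lists camera without trend and median scaling. Of the values of named genes under the alternatives with the same probe set, 2468 of 2494 kept direction and call for denervation in control, 2486 of 2520 in mutant, 843 of 908 for genotype in denervated muscle and 381 of 500 for the interaction. Of list values, 397, 402, 398, 401 and 381 of 418 kept the call and camera's direction, which is relative to the other genes, in the 5 comparisons in the order of the report. Medians of passing lists turned sign with spike-in centring even where that direction stayed. For denervation in control they became 0.36 for fast-fibre, 0.40 for Z-disc, 0.05 for ion channel, 0.12 for respiratory and 0.07 for fatty acid oxidation genes and 0.25 for endothelial markers, where the median of all genes moved to 0.82. For genotype in denervated muscle they became -0.13 for ubiquitin ligase and fatty acid oxidation genes, and for the interaction -0.10 for fatty acid oxidation genes. With median scaling the Z-disc median was 0 for genotype in denervated muscle, and for the interaction 0.12 for fast-fibre, 0.05 for Z-disc and 0.01 for extracellular matrix genes.

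Testing one probe set per gene gave 4585 and 4077 calls for denervation in control and mutant, with fewer features tested. With an estimated correlation 4, 7, 0, 0 and 0 lists passed. Without the trend limma called 279 probe sets for genotype in denervated muscle, 3 in innervated muscle and 10 for the interaction; array weights gave 857 in denervated muscle and 104 for the interaction. Spike-in centring gave 15569 calls for denervation in control and 1396 for genotype in denervated muscle, and the 5'-to-3' covariate 2 in innervated muscle (with 5 lists) and 103 for the interaction. The correlation of denervation changes was 0.51 without a filter and 0.842 with the larger pseudocount. The cause was not tested for these settings. The replicate block gave 7515, 6083, 460, 0 and 45 calls and 17, 15, 7, 4 and 9 lists, and the block in the control arrays alone gave 8312 calls. The block over all arrays gives control and mutant arrays of equal number a shared effect. It therefore does not model a shared animal within a genotype. The interaction uses all groups, so fitting only the groups compared gave no other value.

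Leaving out each array in turn gave 6174 to 7603 calls for denervation in control, 4337 to 8082 in mutant, 223 to 638 for genotype in denervated muscle, 0 to 12 in innervated muscle (3 to 6 lists) and 16 to 108 for the interaction. With 1 innervated mutant array left, that array is assumed to vary like the other groups. Lists that did not pass in the full data passed in opposite directions with the array left out. Proteasome subunits in innervated muscle ranged from -0.10 (camera adjusted p = 0.029) to 0.16 (camera adjusted p = 0.0074). Respiratory genes there ranged from -0.09 (camera adjusted p = 0.005) to 0.26 (camera adjusted p = 3.2e-06), and in the interaction from -0.18 (camera adjusted p = 0.0057) to 0.16 (camera adjusted p = 0.0082). The cause was not tested.

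Of values from other probe sets of the named genes besides Runx1, 65 of 82 kept direction and call for denervation in control and 59 of 71 in mutant. For genotype in denervated muscle 22 of 32 did, and for the interaction 10 of 18. Those that kept the direction without passing were 14, 7, 10 and 8 in these comparisons. Other probe sets of a gene gave other directions in some cases. For denervation in control these were Runx1 (-0.01), Perm1 (0.06) and Mbp (1.05 and 0.57), and in mutant Runx1 (-0.14, with 0.11 on another that did not pass), Mt1 (-0.16), Psmd4 (-0.09), Mbp (0.34 and 1.57) and Xbp1 (-0.02). With spike-in centring, which moves all genes of the denervated arrays up, Mybpc2 (0.05), Tie1 (0.06), Ptprb (0), Esam (0.25) and Fabp4 (0.19) turned for denervation in control. Signal over background limits genes whose lower mean lies within the range of the trp control probe sets, 13.8 to 440.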

Other observations

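The test below was chosen after the list's median had been seen, and its outcome was not known when its bounds were set. Macrophage and leukocyte markers were lower in innervated mutant than in innervated control muscle (median -0.46), and a single array is a candidate explanation. Leaving out each of the 5 innervated arrays in turn gave medians from -0.58 to -0.34, which argues against 1 array as the whole cause. No member passed limma's test and the list did not pass with an estimated correlation (camera adjusted p = 0.6). In the same 5 arrays the medians of extracellular matrix genes (0.44, camera adjusted p = 1.7e-10) and adipocyte markers (0.86, camera adjusted p = 0.0056) were higher in the mutant. Neither list passed with an estimated correlation (camera adjusted p = 0.6 for each), and the adipocyte call also ended without innervated mutant 1 (median 0.53, camera adjusted p = 0.21) or innervated control 1 (camera adjusted p = 0.053). Whether the samples differ in leukocytes or in their mix of tissue was not tested and stays open.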
